A study of Homo sapiens with 24 samples.

How the data were processed

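RNA was measured in A375, an established human melanoma cell line, after transfection with a plasmid that carried the long noncoding RNA SLNCR (symbol LINC00673) or no insert. Per the labels, the plasmid was pcDNA3.1 with a CAG promoter and puromycin resistance, and cells grew for 48 h in 2 µg/mL puromycin before RNA was isolated with RNeasy Plus columns. Per the labels, ribosomal RNA was depleted and libraries were read on an Illumina HiSeq. The 24 libraries form 8 groups of 3 biological replicates. They come as 2 tables of 12 libraries each, called batch 1 and batch 2 here. Each batch holds its own empty vector group and its own full-length SLNCR group (FL). Batch 1 adds SLNCR without triplex-forming region 1 (ΔTFR1) or region 2 (ΔTFR2), and batch 2 adds SLNCR without region 4 (ΔTFR4) or region 5 (ΔTFR5). A triplex-forming region is a stretch of RNA predicted to bind double-stranded DNA.

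The batch 1 table holds raw counts per gene symbol as the authors deposited them, with 28008 genes. The symbols of 27 of its genes had been turned into dates by a spreadsheet, and these entered no gene list. The table holds no mitochondrially encoded gene. The batch 2 table holds estimated counts from salmon as deposited, with 60221 genes named by Ensembl identifier and symbol, of which 1153 repeat a symbol. Of its values, 83.66% are whole within 0.01, and 64.11% of the values above 0 are. The submitters' processing notes name FastQC 0.11.5, cutadapt 2.5, STAR 2.7.3a, featureCounts from Subread 1.6.2 and DESeq2 1.24.0, with the genome builds GRCm38 and GRCh38 and no role for either. Salmon's version, the annotation release and the strand setting are not given in the sources used here. Counts of antisense and overlapping genes, and of genes with near-identical copies such as histone and ribosomal protein genes, are therefore uncertain. The design text says that 6 samples of an earlier series were re-analysed, and it does not say which they are.

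The 2 tables were made in different ways, so they were fitted apart, and no level was compared across them. Totals per library ran from 8627449 to 10789211 counts in batch 1 and from 24810090 to 33063293 in batch 2. The most abundant gene took 1.51 to 1.65% of the counts in batch 1 and 1.51 to 3.31% in batch 2. Estimated counts were rounded to whole numbers. Replicates were compared before averaging, and no pair agreed within sampling noise: chi-square per gene ran from 1.5 to 7.12 in batch 1 and from 8.44 to 221 in batch 2.

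Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM normalisation, and the quasi-likelihood test with robust dispersions. One model per batch covered all 12 libraries, so that 4 groups shared one estimate of the spread. This left 14310 and 18763 genes, with a common biological coefficient of variation of 0.05 and 0.212. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. The prior count for log2 CPM was 2, and a standard error is the log2 fold change divided by the square root of F. CPM values use TMM library sizes. Each batch gives FL against empty vector and each deletion against FL as the 6 main comparisons. Deletion against empty vector and deletion against deletion are secondary, which makes 12 comparisons.

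Gene lists were tested with camera in limma 3.58.1, at a correlation of 0.01, where at least 3 members were tested. The 22 lists were SLNCR-linked genes, matrix proteases and inhibitors, melanocyte differentiation, dedifferentiated melanoma, androgen response, interferon response, inflammatory NF-kB targets, p53 targets, cell cycle, integrated stress response, unfolded protein response, heat shock, cholesterol synthesis, MAPK output, hypoxia, extracellular matrix and mesenchymal genes, oxidative phosphorylation, neuronal and axon guidance genes, markers of other cell types, replication-dependent histones, mitochondrially encoded genes and cytosolic ribosomal proteins. Batch 1 tests 21 of them. The lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. Genes called in FL against empty vector in one batch also served as lists in the other batch, in 20 tests adjusted together.

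The rule for naming genes had 3 parts in each main comparison. It took SLNCR and its linked genes, among them MMP9, CDKN1A, POU4F1 and EGR1. It took the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 1, a gene symbol and groups that do not overlap. It also took the 4 members with the lowest adjusted p of each list with at least 3 called members or past its own test. The rule reaches 54 to 81 genes per main comparison. The text gives these linked genes, many of the largest changes, and up to 4 members of lists past their test; some genes that the rule takes are not reported here. Secondary comparisons name the 3 largest rises and the 3 largest falls. Reversed genes, meaning genes called in FL against empty vector and called the other way in a deletion against FL, and genes called in both batches are named by the smallest larger adjusted p, 10 per comparison at most.

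SLNCR has a gene of its own in batch 1. In batch 2 all 5 of its RefSeq transcripts lie in the Ensembl gene ENSG00000227036, named LINC00511 in the table, so its batch 2 counts hold other LINC00511 transcripts too. Gene GC content and length were known for 94.5% and 98% of tested genes. The relation of each library to GC content is Spearman's rho, across genes, between GC content and the deviation of log2 CPM from the batch mean, and genes are not independent replicates.

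Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter on low counts (a total of at least 1), a model of the 2 compared groups alone, the replicate number as a block, a log2 fold change of at least 1, and each library left out in turn. For lists they were an estimated correlation, limma's fry and camera on DESeq2 statistics. The comparison of batches added a mean log2 CPM of at least 3 in both batches and protein-coding genes alone. Removing each library's GC trend, or its GC and length trends, by loess with a span of 0.3 was added after seeing the data.

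The pipeline was tested on simulated data with 200 changed genes per comparison. For FL against empty vector in batch 1 (14196 genes) it recovered 20% of genes changed 1.2-fold, 74% at 1.5-fold, 84% at 2-fold and 98% at 4-fold, with 11 false calls. In batch 2 (18270 genes) these were 0%, 10%, 60% and 70.8%, with 3 false calls. False calls under the wider spread of FL there were not tested. A simulated GC trend made 2720 of 14194 unchanged genes pass in batch 1, and 7 passed once the trend was removed. In batch 2 these numbers were 3154 of 18296 and 4. Principal components were computed on log2 CPM per batch. Tables were handled with the data.table package (1.17.8), pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.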

Results

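Gene expression was measured by RNA sequencing in 24 libraries of A375 melanoma cells that overexpressed SLNCR, a long noncoding RNA that earlier work links with melanoma invasion, or carried an empty vector. The design asks which genes the triplex-forming regions of SLNCR regulate. Batch 1 held 3 libraries each of empty vector, full-length SLNCR (FL), ΔTFR1 and ΔTFR2, at 8627449 to 10789211 counts per library. Batch 2 held 3 libraries each of empty vector, FL, ΔTFR4 and ΔTFR5, at 24810090 to 33063293. Below, changes are log2 fold changes ± standard error with the adjusted p of edgeR's quasi-likelihood test, and levels are CPM ± SD, each with n = 3 libraries per group.

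SLNCR itself was raised in every group that received it. In batch 1 its level was 20.1 ± 1.04 CPM with empty vector, 208 ± 38.7 with FL, 198 ± 7.14 with ΔTFR1 and 195 ± 10.1 with ΔTFR2. FL exceeded empty vector by 3.37 ± 0.14 (adjusted p = 3.65e-06), a 10.4-fold rise. In batch 2 the level was 29.02 ± 1.12 CPM with empty vector, 574 ± 210 with FL, 486 ± 37.2 with ΔTFR4 and 296 ± 94.5 with ΔTFR5. FL exceeded empty vector by 4.30 ± 0.30 (adjusted p = 4.03e-05). The deletions exceeded empty vector by 3.30 ± 0.14 for ΔTFR1, 3.28 ± 0.14 for ΔTFR2, 4.06 ± 0.30 for ΔTFR4 and 3.35 ± 0.29 for ΔTFR5 (adjusted p = 4.91e-06, 5.2e-06, 1.43e-05 and 6.42e-05).

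No deletion differed from FL in SLNCR level by edgeR's test. The differences were -0.07 ± 0.11 for ΔTFR1 (adjusted p = 0.714), -0.09 ± 0.11 for ΔTFR2 (0.64), -0.24 ± 0.26 for ΔTFR4 (0.618) and -0.95 ± 0.26 for ΔTFR5 (0.0802). DESeq2 called the last of these, at an adjusted p of 0.0115. The FL libraries of batch 2 spread widely, at 728.1, 658.3 and 334.1 CPM, and those of ΔTFR5 lay at 320.8, 375.7 and 191.6. The endogenous gene lies on chromosome 17 at 72403322 to 72592804 (GRCh38, RefSeq annotation), inside the Ensembl gene at 72290091 to 72640472 that holds its batch 2 counts. Those counts also hold other LINC00511 transcripts, and reads cannot tell plasmid from endogenous RNA.

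**Figure D1:**
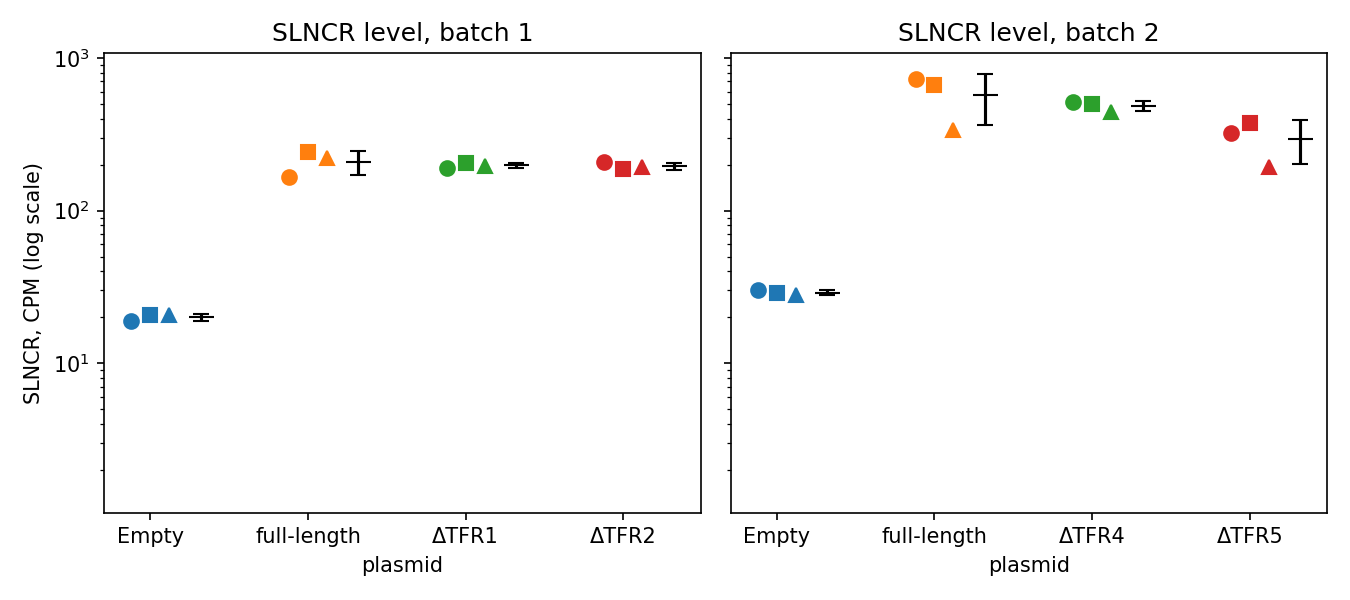
SLNCR level in CPM (log axis) per library in both batches; circles, squares and triangles are replicates 1, 2 and 3, and bars with whiskers give mean and SD, n = 3. Libraries with a construct lie at 165.1 to 728.1 CPM and empty vector libraries at 18.91 to 30.13.

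Among genes that earlier work ties to SLNCR, MMP9, a matrix metalloprotease, was too low to test, with 16 counts over the 12 libraries of batch 1 and 20 over those of batch 2. POU4F1, which encodes the transcription factor Brn3a, lay between 3.23 and 3.74 CPM in batch 1 and between 2.69 and 3.72 in batch 2. It did not pass the test in any of the 12 comparisons. CDKN1A, a cyclin-dependent kinase inhibitor, lay at 269 ± 14 CPM with empty vector and 270 ± 5.16 with FL in batch 1, a difference of 0.00 ± 0.05 (adjusted p = 0.987). With each library's GC trend removed this difference was 0.17 (adjusted p = 0.0343). EGR1, an immediate-early transcription factor, differed by -0.19 ± 0.11 (adjusted p = 0.188).

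In batch 2 EGR1 lay at 22.6 ± 3.89 CPM with empty vector, 330 ± 263 with FL, 714 ± 106 with ΔTFR4 and 229 ± 205 with ΔTFR5. Its excess in FL over empty vector was 3.87 ± 1.06 (adjusted p = 0.08; DESeq2 0.00304), and in ΔTFR4 over empty vector 4.98 ± 1.12 (adjusted p = 0.0121). CDKN1A lay at 214 ± 9.59 CPM with empty vector, 267 ± 54.8 with FL, 383 ± 58.4 with ΔTFR4 and 209 ± 60 with ΔTFR5. It rose by 0.84 ± 0.20 in ΔTFR4 against empty vector (adjusted p = 0.0103). Its difference in FL against empty vector was 0.32 ± 0.20 (adjusted p = 0.312). None of the tested linked genes passed in ΔTFR4 or ΔTFR5 against FL: EGR1 differed by 1.11 ± 0.95 (adjusted p = 0.517) and -0.53 ± 0.94 (0.787), and CDKN1A by 0.52 ± 0.20 (0.146) and -0.36 ± 0.20 (0.333). The list of SLNCR-linked genes, with 4 tested members, had an adjusted p of 0.949 in FL against empty vector in batch 1 and 0.719 in batch 2, with 0 members called in either.

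FL against empty vector in batch 1 gave many small differences. DNAJB9, a co-chaperone of the endoplasmic reticulum, rose by 0.61 ± 0.11 (adjusted p = 0.000703), from 17.2 ± 1.72 to 26.4 ± 2.45 CPM. The noncoding LINC01419 rose by 0.90 ± 0.25 (0.0118), NUDT7, a peroxisomal coenzyme A hydrolase, by 0.88 ± 0.30 (0.033) and the vitamin D 25-hydroxylase CYP2R1 by 0.83 ± 0.28 (0.0293). COX17, a copper chaperone of cytochrome c oxidase, fell by 1.19 ± 0.23 (adjusted p = 0.00108), from 6.2 ± 1.19 to 2.68 ± 0.93 CPM.

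Other falls were malonyl-CoA decarboxylase MLYCD at -0.93 ± 0.20 (0.00175) and the BMP antagonist CHRDL1 at -0.91 ± 0.31 (0.0327). NME2, which shares sequence with NME1, fell by 0.91 ± 0.28 (0.0182) and the lysoplasmalogenase TMEM86B by 0.87 ± 0.22 (0.00606). DNAJB9, COX17 and MLYCD also passed once GC trends were removed (adjusted p = 0.0159, 0.00519 and 0.0291). For the other genes of this and the preceding paragraph except SLNCR the GC-removed adjusted p was 0.0809 or higher.

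Replication-dependent histones, the core histones made for DNA replication, fell as a list: of 57 tested, 0 rose, 35 fell and 22 did not pass, with a median of -0.37 (camera, adjusted p = 9.28e-18; adjusted p = 0.746 with an estimated correlation). Adjusted over the list alone, 49 fell. HIST2H2BF fell by 0.36 ± 0.07 (0.00103) and HIST1H2BN by 0.40 ± 0.08. Cytosolic ribosomal proteins fell as a list with a median of -0.11, 2 of 77 rising and 16 falling (adjusted p = 9.48e-06; adjusted p = 0.78 with an estimated correlation), and 2 and 22 when adjusted over the list alone. RPS3A rose by 0.25 ± 0.04 (0.000703). Histone and ribosomal protein genes share reads with near-identical copies and are uncertain. With these lists moved the GC trend of the libraries: the trend ran from -0.61 to -0.38 in FL libraries and from 0.12 to 0.53 with empty vector. With GC trends removed the lists still fell, with medians of -0.26 and -0.11 (adjusted p = 1.07e-20 and 1.98e-08), and with GC and length trends removed with -0.185 and -0.09 (4.21e-13 and 2.86e-05).

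By camera the other 19 lists did not pass in this comparison. By fry, which tests whether the genes of a list move one way and does not compare them with other genes, 5 of them passed: the integrated stress response and markers of other cell types downward (adjusted p = 0.0215 for both), extracellular matrix genes downward (0.0424), and neuronal genes (0.0215) and the unfolded protein response (0.0375) upward. The largest list medians among them were in markers of other cell types (-0.22; 0 of 5 rose and 2 fell, 0 and 3 over the list alone; adjusted p = 0.144) and the integrated stress response (-0.17; 1 of 20 rose and 6 fell, 2 and 9 over the list alone; adjusted p = 0.0719). Oxidative phosphorylation genes had a median of -0.12 (1 of 25 rose, 3 fell; 0 and 3 over the list alone; adjusted p = 0.0595). Of 30 cell cycle genes 5 rose and 7 fell, of 22 p53 targets 5 and 4, of 22 dedifferentiated melanoma genes 5 and 3, and of 19 cholesterol synthesis genes 4 and 4. Of 17 androgen response genes 4 rose and 0 fell, of 15 unfolded protein response genes 4 and 1, of 15 neuronal genes 2 and 0, and of 25 extracellular matrix genes 1 and 5. MAPK output genes gave 1 and 4 of 19, heat shock 2 and 2 of 12, hypoxia 2 and 2 of 16, NF-kB targets 2 and 1 of 17, interferon response 1 and 0 of 23, matrix proteases 1 and 1 of 23 and melanocyte genes 0 of 12. Counts over the list alone for these lists were within 2 of the counts given.

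In all, 3247 of 14310 genes were called in FL against empty vector in batch 1, 1634 higher and 1613 lower, with a median absolute log2 fold change of 0.261, and 22 changed by at least 1 on the log2 scale. Across genes, which are not independent replicates, the log2 fold change went with GC content (Spearman's rho = -0.69): median GC was 39.4% in genes that rose and 59.8% in genes that fell. With GC trends removed 281 genes were called, 209 of them among the 3247. The 2 groups alone gave 2108. Without empty vector replicate 1 the count was 1182 (737 higher and 445 lower), without empty vector replicate 2 it was 1934 and without FL replicate 3 it was 1721.

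**Figure D2:**
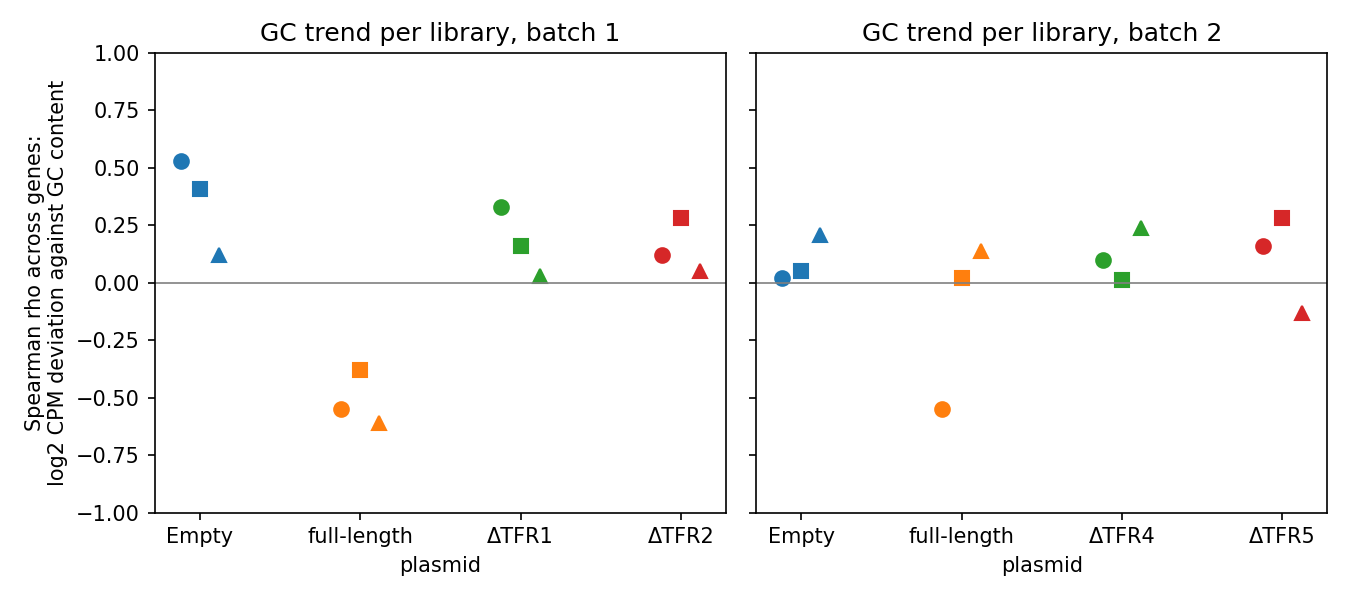
Relation of each library's log2 CPM deviation from the batch mean to gene GC content, as Spearman's rho across genes, in both batches; circles, squares and triangles are replicates 1, 2 and 3. FL libraries of batch 1 lie at -0.61 to -0.38, all other libraries of batch 1 at 0.03 to 0.53, and FL replicate 1 of batch 2 at -0.55.

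ΔTFR1 against FL asks which genes need region 1. Of the genes above, COX17 rose by 0.96 ± 0.24 (0.0154), TMEM86B by 1.11 ± 0.22 (0.00536) and NME2 by 1.03 ± 0.28 (0.0207), and LINC01419 fell by 0.88 ± 0.26 (0.0302). NRIP2, a nuclear receptor interacting protein, rose by 1.01 ± 0.23 (adjusted p = 0.0101). The adaptor LIME1 rose by 0.85 ± 0.18 (0.00897). CDKL3, a kinase, fell by 1.12 ± 0.33 (0.0318), the homeobox factor PRRX1 by 0.91 ± 0.27 (0.0317), epsilon-tubulin TUBE1 by 0.61 ± 0.12 (0.00633) and SCOC by 0.55 ± 0.10 (0.00767). SCOC alone of these passed with GC trends removed (-0.38, adjusted p = 0.0462).

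Histones rose as a list in ΔTFR1 against FL: 9 of 57 rose, 0 fell and 48 did not pass, and 21 rose when adjusted over the list alone (median 0.26, adjusted p = 4.66e-12; adjusted p = 0.793 with an estimated correlation). HIST2H2BF rose by 0.26 ± 0.07 (0.019; 0.0973 with GC trends removed). The GC trend ran from 0.03 to 0.33 in ΔTFR1 libraries and from -0.61 to -0.38 in FL. Ribosomal proteins rose with a median of 0.06, 4 of 77 rising and 1 falling (0 and 1 over the list alone; adjusted p = 0.0103; adjusted p = 0.793 with an estimated correlation). Their call was lost without FL replicate 3 (0.65), ΔTFR1 replicate 2 (0.521) or 3 (0.0608). It held with GC removed (0.0139), but not with length too (0.0814, median 0.05, histones 0.12). Of the other 19 lists none passed by camera: 7 of 30 cell cycle genes fell and 2 rose, with a list adjusted p of 0.454.

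In all, 1440 genes were called in ΔTFR1 against FL, 630 higher and 810 lower. The share of higher genes was 43.8%, 31.5% by DESeq2 (424 and 922) and 28% in a model of these 2 groups alone (85 and 219), which kept 10 of 48 called genes the naming rule took. The log2 fold change went with GC content across genes (rho = 0.63), and 10 genes were called with GC trends removed, 9 of them among the 1440. The count was 804 without FL replicate 1, 2752 without FL replicate 2, 283 without FL replicate 3 (47 and 236), 22 without ΔTFR1 replicate 1 (1 and 21) and 788 without ΔTFR1 replicate 2, and 0 of the 48 passed in all of these fits.

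ΔTFR2 against FL gave similar numbers. PLPP4, a phospholipid phosphatase, rose by 1.14 ± 0.21 (adjusted p = 0.00732), from 2.23 ± 0.33 to 4.95 ± 0.2 CPM, and CCDC151, a dynein arm docking factor, by 0.90 ± 0.14 (0.00435). Both passed with GC trends removed (0.0372 and 0.00909), as did caveolin CAV2, which fell by 0.47 ± 0.09 (0.0108; 0.0406 with GC trends removed). NME2 rose by 1.03 ± 0.27 (0.0204), COX17 by 0.95 ± 0.24 (0.0153) and the transcription factor BATF3 by 0.87 ± 0.28 (0.0441). LINC01419 fell by 0.81 ± 0.25 (0.0407), and vesicle fusion genes NAPB and VAMP4 fell by 0.57 ± 0.17 (0.0304) and 0.56 ± 0.17 (0.0324). CDKN1A rose by 0.14 ± 0.05 (0.045), which was 0.01 (0.956) with GC trends removed.

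Of 57 histones 8 rose and 49 did not pass, 24 rising when adjusted over the list alone (median 0.25, adjusted p = 3.76e-13; adjusted p = 0.424 with an estimated correlation). Of 77 ribosomal proteins 10 rose and 1 fell (14 and 1 over the list alone; median 0.11, adjusted p = 6.85e-07; adjusted p = 0.424 with an estimated correlation). Oxidative phosphorylation genes rose as a list with a median of 0.10, with 1 of 25 called, NDUFS5 of complex I at 0.35 (0.0202; 0.0729 with GC trends removed). The list's adjusted p was 0.011 (0.424 with an estimated correlation), 0.0752 without FL replicate 3 and 0.124 without ΔTFR2 replicate 2. With GC trends removed it was 0.00191, and with length too 0.133 (median 0.10, histones 0.12 and ribosomal proteins 0.06). The GC trend ran from 0.05 to 0.28 in ΔTFR2 libraries. The other 18 lists did not pass by camera, among them p53 targets with 5 of 22 rising (6 and 1 over the list alone; adjusted p = 0.172, and 0.00488 by fry).

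In all, 1432 genes were called in ΔTFR2 against FL, 695 higher and 737 lower, and 30 with GC trends removed, 24 of them among the 1432 (rho with GC content across genes 0.62). The 2 groups alone gave 724 and kept 30 of 46 called genes the naming rule took. Without FL replicates 1, 2 and 3 the counts were 771, 2710 and 185 (60 higher and 125 lower). Without ΔTFR2 replicates 1, 2 and 3 they were 671, 0 and 411; at the 0, edgeR gave 2802 genes at an unadjusted p under 0.05, and 0 of the 46 passed in all of these fits.

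Against empty vector, the deletions of batch 1 gave almost no called genes. ΔTFR1 raised SLNCR alone (589 genes at an unadjusted p under 0.05). ΔTFR2 raised SLNCR and the cytokine IL24, by 0.41 ± 0.07 (adjusted p = 0.00668). The IL24 call was lost without empty vector replicate 1 (0.0943) or 2 (0.137) or without ΔTFR2 replicate 1 (0.216) or 3 (0.16). ΔTFR2 against ΔTFR1 gave 0 genes by edgeR (551 at an unadjusted p under 0.05) and 0 by DESeq2 (291). As lists against empty vector, histones had medians of -0.09 in ΔTFR1 (adjusted p = 2.13e-07) and -0.10 in ΔTFR2 (3e-06), with 0 members called, and 0 and 1 falling over the list alone. Both calls were lost without empty vector replicate 1 (0.364 and 0.242). The p53 targets rose as a list in ΔTFR2 with a median of 0.10 (adjusted p = 0.00106), 0 of 22 called and 4 over the list alone. In ΔTFR1, melanocyte genes rose as a list (0.10, adjusted p = 0.0148) and cell cycle (-0.04, 0.0121), integrated stress response (-0.07, 0.00576) and ribosomal protein genes (-0.05, 7.57e-05) fell, with 0 members called. Each of these was lost without empty vector replicate 1 (0.385 for melanocyte, 0.104 for stress and 0.191 for ribosomal protein genes) or ΔTFR1 replicate 1 (0.145 for cell cycle, 0.111 for melanocyte and 0.111 for ribosomal protein genes). In ΔTFR2 against ΔTFR1, ribosomal proteins rose as a list (0.04, adjusted p = 0.00267), lost without ΔTFR1 replicate 1 (0.444) or ΔTFR2 replicate 2 (0.399) or with GC and length trends removed (0.117). With both trends removed the medians against empty vector were -0.05 for histones, -0.05 for stress and -0.03 for ribosomal protein genes in ΔTFR1 and 0.06 for p53 targets in ΔTFR2. With an estimated correlation the smallest adjusted p of any list in these 3 comparisons was 0.0566, for p53 targets.

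Genes that changed with FL and went back with a deletion were counted in batch 1. Of the 3247 called in FL against empty vector, 1266 (39%) were called the other way in ΔTFR1 against FL, 735 of them up then down and 531 down then up. For ΔTFR2 these numbers were 1257 (38.7%), 669 and 588. Single libraries moved both: the numbers for ΔTFR1 and ΔTFR2 were 262 and 175 without FL replicate 3, 717 and 695 without FL replicate 1, 2472 and 2455 without FL replicate 2, and 782 and 741 without empty vector replicate 1. They were 22 and 680 without ΔTFR1 replicates 1 and 2, 607, 0 and 376 without ΔTFR2 replicates 1, 2 and 3 (edgeR; 2802 genes at an unadjusted p under 0.05 in ΔTFR2 against FL without replicate 2), and 831 for ΔTFR2 without empty vector replicate 2. Removal of GC trends left 9 and 23 such genes, 8 and 18 of them among the 1266 and 1257.

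Both steps share the FL libraries, so opposite changes arise by chance. Unchanged groups simulated in the same layout gave a mean of 0 reversed genes for ΔTFR1 and 0.1 for ΔTFR2, but they carried no GC trend, while the FL libraries do: with a GC trend simulated in FL against empty vector, 2720 unchanged genes were called. Independent lists of these sizes would share 92.5 and 71 genes for ΔTFR1 (up then down, and down then up) and 84.2 and 78.3 for ΔTFR2. The covariance of the log2 fold changes was -0.0424 and -0.0419, against -0.0141 and -0.0142 simulated. ΔTFR1 and ΔTFR2 against FL shared 817 genes in the same direction, 327 higher and 490 lower, where independent lists would share 30.6 and 41.7 and simulation at most 1, with a covariance of 0.0358 against 0.0143. With 3 shared libraries no split leaves 2 in each part, so in both batches part of any excess may come from the shared libraries.

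FL against empty vector in batch 2 gave fewer and larger called differences. In simulation 1.5-fold changes were mostly missed (10% found, 74% in batch 1). TXNIP, a thioredoxin inhibitor, rose by 4.19 ± 0.80 (adjusted p = 0.0458), from 33.5 ± 7.84 to 612 ± 503 CPM, and ARRDC4 by 2.79 ± 0.57 (0.0433). DDIT3, the stress factor CHOP, rose by 2.28 ± 0.46 (0.0431), and PPP1R15A by 2.42 ± 0.45 (0.0425). HDGFL1 rose by 3.61 ± 0.46 (0.00587), the immune receptor OSCAR by 3.13 ± 0.62 (0.0431) and the transcription factor CREB5 by 2.57 ± 0.36 (0.0139).

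Falls were smaller. CTNND2, a delta-catenin, fell by 1.31 ± 0.15 (adjusted p = 0.00369), from 17.4 ± 1.52 to 7.01 ± 0.87 CPM. The reticulon RTN1 fell by 1.16 ± 0.17 (0.0149) and the protease inhibitor SERPINA3 by 1.07 ± 0.22 (0.0431). CIITA, the regulator of MHC class II genes, fell by 1.06 ± 0.22 (0.0458) and the class II gene HLA-DRA by 1.03 ± 0.20 (0.0431). The metallothionein MT1X fell by 1.02 ± 0.22 (0.0496) and the death-associated kinase DAPK1 by 1.00 ± 0.17 (0.0322).

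Of the 22 lists 12 passed, 5 up and 7 down. Integrated stress response genes rose, 6 of 20 called and 14 over the list alone (median 0.90, adjusted p = 5.57e-10; adjusted p = 0.227 with an estimated correlation), with STC2 at 1.95 ± 0.36 (0.0414), TRIB3 at 1.68 ± 0.33 (0.0425) and SESN2 at 1.79 ± 0.35 (0.0431). Dedifferentiated melanoma genes rose, 3 of 22 (13 up and 2 down over the list alone; median 0.42, adjusted p = 0.000318; adjusted p = 0.227 with an estimated correlation), with the growth factor receptor EGFR at 0.95 ± 0.21 (0.0496) and SOX9 at 0.62 ± 0.12. MAPK output genes rose, 2 of 19 (10 and 1 over the list alone; 0.40, adjusted p = 0.000739; adjusted p = 0.227 with an estimated correlation), with MYC at 1.82 ± 0.39 (0.0496). NF-kB targets rose with 1 of 19 called, the cytokine LIF at 1.19 ± 0.26 (0.0496), and 7 over the list alone (0.49, adjusted p = 0.00771; adjusted p = 0.531 with an estimated correlation). The p53 targets rose with 2 of 22 called, among them GDF15 at 2.10 ± 0.41 (0.0425), and 7 over the list alone (0.25, adjusted p = 0.00863; adjusted p = 0.531 with an estimated correlation).

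The lists that fell had almost no called member. Heat shock genes had a median of -0.98, 0 of 12 called and 11 over the list alone (adjusted p = 3.15e-09; adjusted p = 0.227 with an estimated correlation); the chaperones HSPA8 and HSP90AA1 stood at -1.49 ± 0.47 (0.0919) and -1.005 ± 0.26 (0.0651). Cell cycle genes had -0.50, 0 of 30 called and 0 over the list alone (3.15e-09; adjusted p = 0.495 with an estimated correlation), with the replication factors CDC6 at -0.98 ± 0.28 (0.0778) and PCNA at -0.97 ± 0.32 (0.0978). Cholesterol synthesis genes had -0.55, 0 of 19 called and 10 falling over the list alone (1.86e-05; adjusted p = 0.227 with an estimated correlation), with INSIG1 at -0.85 ± 0.21 (0.0608). Interferon response genes had -0.41, 0 of 28 called and 8 over the list alone (3.34e-05; adjusted p = 0.227 with an estimated correlation), with IFIT1 at -2.06 ± 0.55 (0.0669). Oxidative phosphorylation genes had -0.37, 0 of 25 called either way (2.01e-05; adjusted p = 0.531 with an estimated correlation), and histones -0.19, 0 of 64 called either way (0.00141; adjusted p = 0.764 with an estimated correlation). Matrix proteases and inhibitors had a median of -0.30, with 1 of 25 rising, 1 falling, TIMP3 by -0.98 ± 0.20 (0.0433), and 23 not passing, and 3 up and 5 down over the list alone (adjusted p = 0.0434; adjusted p = 0.531 with an estimated correlation; 0.185 with GC trends removed).

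Leaving out libraries ended some of these calls. Without FL replicate 1 the adjusted p was 0.0653 for NF-kB targets, 0.23 for matrix proteases and 0.28 for histones, whose median then was 0.12. Without FL replicate 2 it was 0.0704 for NF-kB targets and 0.0628 for p53 targets, and without empty vector replicate 3 it was 0.0878 for matrix proteases. Removal of GC trends left medians of 0.14 for p53 targets and -0.12 for histones. Lists that did not pass by camera were melanocyte genes (0 up, 1 down of 15; 1 and 1 over the list alone; adjusted p = 0.654), androgen response (1 up of 19; 2 and 1; 0.719), unfolded protein response (0 of 15; 2 and 4; 0.719), hypoxia (0 of 17; 2 and 0; 0.865), extracellular matrix (1 up of 26; 4 and 1; 0.24), neuronal (0 of 21; 3 and 3; 0.654), markers of other cell types (0 of 17; 0 and 1; 0.943), mitochondrially encoded (0 of 12; 0.719) and ribosomal protein genes (0 of 78; 0.0566).

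In all, 217 of 18763 genes were called in FL against empty vector in batch 2, 193 higher and 24 lower, with a median absolute log2 fold change of 1.343, and 4933 genes had an unadjusted p under 0.05. A model of these 2 groups alone called 2 genes and kept 1 of 33 called genes the naming rule took. The share of higher genes was 88.9%, 70.8% by DESeq2 (1379 higher and 568 lower), 55.1% without FL replicate 3 (3290 and 2676), 76% without FL replicate 1 (38 and 12), 45% without empty vector replicate 3 (9 and 11) and 78.6% with GC and length trends removed. FL replicate 1 stood apart on the second principal component, at 95.1 against -29.4 to 12.9 for the other libraries, and had a GC trend of -0.55 against -0.13 to 0.28. The count was 50 without FL replicate 1, 12 without FL replicate 2 and 5966 without FL replicate 3. It was 6, 12 and 20 without empty vector replicates 1, 2 and 3, 27, 26 and 27 without ΔTFR4 replicates 1, 2 and 3, and 21, 29 and 30 without ΔTFR5 replicates 1, 2 and 3. SLNCR and CTNND2 alone of the 33 passed in every one of the fits that leave out 1 library. With GC trends removed 774 genes were called, 215 of them among the 217.

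**Figure D3:**
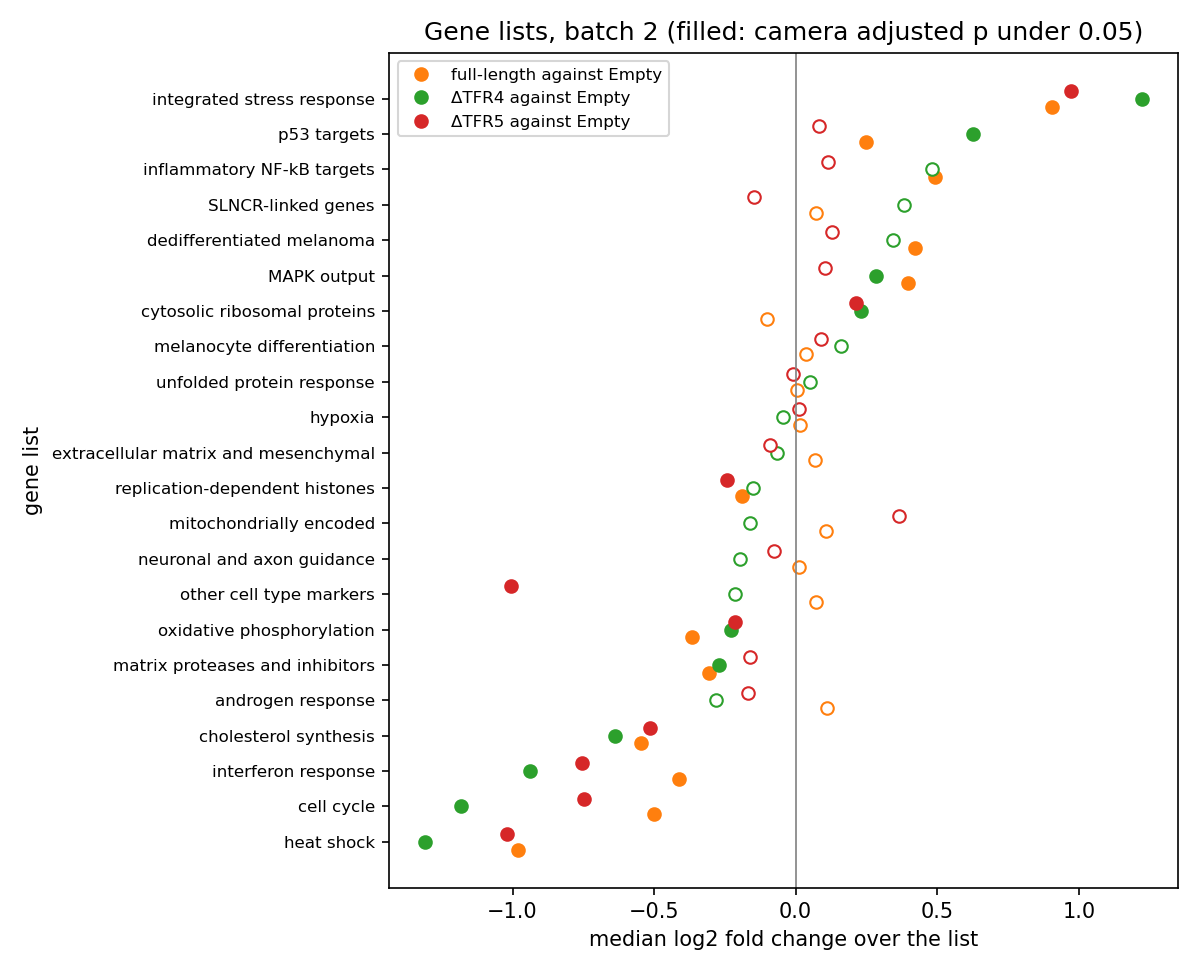
Median log2 fold change against empty vector of the 22 gene lists in batch 2 for FL, ΔTFR4 and ΔTFR5, n = 3 libraries per group; filled points have a camera adjusted p under 0.05 at a preset correlation of 0.01. Integrated stress response genes lie at 0.90, 1.22 and 0.97, and cell cycle genes at -0.50, -1.18 and -0.75.

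In ΔTFR4 against FL, SERPINA3, an acute-phase protease inhibitor, fell by 4.38 ± 0.29 (adjusted p = 9.66e-06), from 11.7 ± 2.48 to 0.556 ± 0.031 CPM. Alpha-2-macroglobulin A2M fell by 3.25 ± 0.31 (0.000216), and the collagenase MMP1 by 2.92 ± 0.61 (0.022). Falls of other secreted factors were -2.84 ± 0.34 for the urocortin UCN2 (0.00155) and -2.09 ± 0.51 for the stromelysin MMP3 (0.0413), and GAS7 changed by -2.55 ± 0.32 (0.00227). RRM2, a subunit of ribonucleotide reductase, fell by 1.79 ± 0.24 (0.00317), the noncoding DLEU2 by 1.68 ± 0.29 (0.00935) and the linker histone HIST1H1A by 2.05 ± 0.35 (0.00944). Rises were led by the teneurin TENM1 at 2.71 ± 0.24 (0.000114), from 5.18 ± 0.9 to 34.1 ± 1.45 CPM, the mucin MUC2 at 2.68 ± 0.23 (0.000114) and the synaptic scaffold DLGAP1 at 2.499 ± 0.25 (0.000253).

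The axonemal dynein DNAH1 rose by 2.22 ± 0.29 (0.00227), the secreted protease HTRA1 by 2.11 ± 0.17 (6.14e-05), the lipid transporter ABCA3 by 1.86 ± 0.27 (0.00419) and the transcription factor POU6F1 by 1.75 ± 0.30 (0.00935). All of the genes of this and the preceding paragraph passed with GC trends removed, except MMP3 (adjusted p = 0.0548). Leaving out 1 library gave adjusted p-values of up to 0.178 for MMP3, 0.115 for MMP1, 0.0651 for HIST1H1A, 0.0566 for DLEU2 and 0.052 for POU6F1, and below 0.05 for the others. A model of these 2 groups alone kept 14 of the 44 called genes the naming rule took.

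Cell cycle genes fell as a list in ΔTFR4 against FL: 6 of 30 fell, 24 did not pass, and 24 fell over the list alone (median -0.71, adjusted p = 3.45e-14; adjusted p = 0.527 with an estimated correlation). The checkpoint kinase gene BUB1B fell by 0.85 ± 0.15 (0.012), cyclin A2 (CCNA2) by 1.23 ± 0.26 (0.0228) and the motor KIF11 by 0.72 ± 0.17 (0.032). Ribosomal proteins rose as a list with 0 of 78 called either way (0.35, adjusted p = 3.61e-09; adjusted p = 0.527 with an estimated correlation). The p53 targets rose, 1 of 22 called, ZMAT3 at 0.57 ± 0.14 (0.035), and 3 over the list alone (0.33, adjusted p = 0.000665; adjusted p = 0.527 with an estimated correlation). Integrated stress response genes rose with 1 of 20 called either way, the stress protein gene NUPR1 at 1.39 ± 0.34 (0.0378; list 0.27, adjusted p = 0.0134; adjusted p = 0.549 with an estimated correlation). Interferon response genes fell with 2 of 28 called, OAS2 at -0.77 ± 0.19 (0.0419) and HERC5 at -1.01 ± 0.26 (0.0463), 1 up and 3 down over the list alone (-0.36, adjusted p = 0.0266; adjusted p = 0.527 with an estimated correlation).

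Extracellular matrix genes fell as a list with members in both directions, 2 of 26 rising and 3 falling, 2 and 8 over the list alone (-0.26, adjusted p = 0.0266; adjusted p = 0.527 with an estimated correlation). Thrombospondin THBS1 fell by 1.16 ± 0.12 (0.000519) and the integrin ITGB3 by 1.44 ± 0.17 (0.0012), while collagen COL6A3 rose by 1.41 ± 0.20 (0.00419). Without FL replicate 3 the adjusted p was 0.443 for the stress and for the interferon list and 0.0944 for the matrix list; it was 0.0656 for the matrix list without FL replicate 2. Without ΔTFR4 replicate 2 it was 0.0681 for the interferon and for the matrix list, and without ΔTFR4 replicate 3 it was 0.0554 for the interferon list, which was at 0.0532 with GC and length trends removed. Removal of GC trends left medians of 0.19 for p53 targets and 0.17 for the stress list. The other 16 lists did not pass by camera, with 4 of 19 androgen response genes falling (7 over the list alone; adjusted p = 0.057, and 0.0315 by fry), 0 of 15 melanocyte genes called (2 falling over the list alone; median 0.25, 0.242, and 0.0228 upward by fry), 3 of 22 dedifferentiated melanoma genes falling (3; 0.105) and 1 of 25 matrix proteases rising, MMP11 at 1.72 ± 0.36 (0.0218), and 2 falling (3 and 4; 0.361).

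In all, 819 genes were called in ΔTFR4 against FL, 356 higher and 463 lower, and 1453 with GC trends removed, 690 of them among the 819. The 2 groups alone gave 33, 16 higher and 17 lower. Without empty vector replicates 1, 2 and 3 the count was 402, 425 and 439, without FL replicates 1, 2 and 3 it was 1708, 1576 and 2220, without ΔTFR4 replicates 1, 2 and 3 it was 114 (68 higher and 46 lower), 79 and 168, and without ΔTFR5 replicate 1 it was 441.

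In ΔTFR5 against FL, HMCN1, a matrix protein, rose by 2.04 ± 0.24 (adjusted p = 0.00221), the proteoglycan SDC3 by 1.67 ± 0.17 (0.000855), from 7.95 ± 1.73 to 25.4 ± 1.73 CPM, and the transcription factor SOX5 by 1.49 ± 0.19 (0.00376). DNAH1 rose by 1.97 ± 0.29 (0.00863), the serpin SERPINF1 by 1.71 ± 0.29 (0.0168) and SERPINA3 by 1.56 ± 0.22 (0.00813). The drug efflux pump ABCB1 fell by 2.10 ± 0.21 (0.00087), from 6.82 ± 0.94 to 1.58 ± 0.27 CPM, and RGS2 by 2.02 ± 0.36 (0.0216).

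The basal keratin KRT14 fell by 1.69 ± 0.38 (0.0484), the EGF receptor ligand HBEGF by 1.68 ± 0.34 (0.0336), DLEU2 by 1.61 ± 0.29 (0.0208) and KITLG by 1.52 ± 0.27 (0.0216). Keratins share reads with relatives and are uncertain. All of the genes of this and the preceding paragraph also passed with GC trends removed. Of 31 called genes the naming rule took, 7 passed without each library in turn, and 0 in a model of these 2 groups alone.

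Of the lists 7 passed in ΔTFR5 against FL. Markers of other cell types fell, with KRT14 as the 1 called of 17 and 6 over the list alone (median -0.91, adjusted p = 0.000186; adjusted p = 0.307 with an estimated correlation); the other keratins KRT10 and KRT1 stood at -0.91 (0.051) and -1.67 (0.0696). Ribosomal proteins rose with 0 of 78 called either way (0.28, adjusted p = 4.21e-07; adjusted p = 0.781 with an estimated correlation). Cell cycle genes fell with 1 of 30 called either way, RRM2 at -1.12 ± 0.24 (0.0407; list -0.26, adjusted p = 0.00234; adjusted p = 0.855 with an estimated correlation). Dedifferentiated melanoma genes fell as a list: the matricellular genes CCN2 and CCN1 fell by 1.22 ± 0.20 (0.0155) and 0.94 ± 0.20 (0.042), tenascin TNC rose by 0.55 ± 0.12 (0.0392), 19 of 22 did not pass, and 1 rose and 6 fell over the list alone (-0.28, adjusted p = 0.00897; adjusted p = 0.388 with an estimated correlation).

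NF-kB targets fell, with the cytokines CSF2 at -2.69 ± 0.51 (0.0262) and CXCL1 at -0.80 ± 0.17 (0.0373) as the 2 called of 19 and 6 over the list alone (-0.38, adjusted p = 0.00897; adjusted p = 0.781 with an estimated correlation). Androgen response genes fell, with ELL2 at -0.93 ± 0.20 (0.0435) and ACSL3 at -0.61 ± 0.14 (0.0484) as the 2 called of 19, and 2 up and 7 down over the list alone (median -0.46, adjusted p = 0.0362; adjusted p = 0.371 with an estimated correlation). MAPK output genes fell with 0 of 19 called and 3 over the list alone (-0.19, adjusted p = 0.00918; adjusted p = 0.538 with an estimated correlation). Without FL replicate 3 the adjusted p was 0.92 for the cell cycle and 0.0839 for the androgen list; without FL replicate 1 it was 0.112 for the NF-kB and 0.055 for the androgen list; without FL replicate 2 it was 0.118 for the NF-kB and 0.13 for the MAPK list. Without ΔTFR5 replicate 2 it was 0.1 for the cell cycle and 0.06 for the androgen list, and without ΔTFR5 replicate 3 it was 0.173 for the NF-kB list.

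Extracellular matrix genes went both ways in ΔTFR5 against FL, with fibronectin FN1 up by 0.91 ± 0.14 (0.0108), COL6A3 up by 0.93 ± 0.20 and THBS1 down by 1.28 ± 0.12 (0.000855), 3 of 26 rising and 2 falling (4 and 5 over the list alone; list adjusted p = 0.648). Melanocyte genes, 1 of 15 falling (2 up and 1 down over the list alone; median 0.22), did not pass by camera (0.219) and passed upward by fry (0.0125). In all, 259 genes were called, 155 higher and 104 lower (59.8% higher), and 1 in a model of these 2 groups alone. Some other settings gave more lower than higher genes: 588 and 811 by DESeq2 (42% higher), 232 and 254 with no filter, and 384 and 484 with GC trends removed, 236 of these 868 among the 259. The count was 596 without FL replicate 1 (287 and 309), 3480 without FL replicate 3 (1394 and 2086), 102, 116 and 127 without empty vector replicates 1, 2 and 3, 114, 103 and 111 without ΔTFR4 replicates 1, 2 and 3, and 31, 19 and 399 without ΔTFR5 replicates 1, 2 and 3.

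In ΔTFR4 against empty vector 4489 genes were called, 2342 higher and 2147 lower. TXNIP rose by 5.15 ± 0.83 (0.00275), EGR1 by 4.98 ± 1.12 (0.0121) and OSCAR by 4.69 ± 0.63 (0.000782), while SERPINA3 fell by 5.45 ± 0.29 (1.42e-06) and A2M changed by -4.02 ± 0.31 (1.91e-05). Cell cycle genes fell, 28 of 30 called and 29 over the list alone (median -1.18, adjusted p = 1.86e-23). Heat shock genes fell, 11 of 12 called and 12 over the list alone (-1.31, 2.61e-08), interferon response genes 17 of 28 (2 up and 18 down over the list alone; -0.94, 1.35e-06) and cholesterol synthesis genes 9 of 19 (11; -0.64, 3.97e-06). Integrated stress response genes rose, 15 of 20 (17 and 1 down; 1.22, 2.88e-11), as did p53 targets, 13 of 22 (14; 0.63, 3.97e-06). These 6 lists had an adjusted p of 0.224 with an estimated correlation.

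With smaller shares called, MAPK output (7 up and 1 down of 19; 0.28, adjusted p = 0.0432) and ribosomal protein genes (4 up and 1 down of 78; 0.23, 0.00732) rose as lists in ΔTFR4. Matrix proteases (2 up and 8 down of 25; -0.27, 0.0466) and oxidative phosphorylation genes (2 down of 25; -0.23, 0.0407) fell. These 4 had an adjusted p of 0.483 to 0.686 with an estimated correlation, and over the list alone 8 and 1, 1 and 0, 2 and 8, and 0 members passed. The adjusted p with GC trends removed was 0.132 for matrix proteases (0.0739 by DESeq2), 0.0511 for oxidative phosphorylation and 0.0699 for MAPK output. Without empty vector replicate 3 it was 0.0563 for MAPK output, 0.08 for matrix proteases and 0.163 for oxidative phosphorylation; without ΔTFR4 replicate 2 it was 0.156 for the last 2, and without ΔTFR4 replicate 1 it was 0.0532 for ribosomal proteins. The count of 4489 was 9081 with the 2 groups alone, 2691, 2719 and 2494 without empty vector replicates 1, 2 and 3, 7329 without FL replicate 1 and 2697, 2309 and 2914 without ΔTFR4 replicates 1, 2 and 3.

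In ΔTFR5 against empty vector 1907 genes were called, 1028 higher and 879 lower. TXNIP rose by 4.40 ± 0.81 (0.0106), OSCAR by 4.21 ± 0.63 (0.00247) and HDGFL1 by 3.52 ± 0.47 (0.00143), while osteopontin SPP1 fell by 2.63 ± 0.46 (0.00554) and the vitamin D hydroxylase CYP24A1 changed by -2.51 ± 0.37 (0.00245). Cell cycle genes fell, 16 of 30 called and 27 over the list alone (-0.75, adjusted p = 6.04e-17), heat shock genes 4 of 12 (12; -1.02, 3.26e-09), cholesterol synthesis genes 8 of 19 (12; -0.51, 3.26e-09), interferon response genes 11 of 28 (1 up and 19 down; -0.75, 3.94e-08) and markers of other cell types 3 of 17 (7; 0.00108). Integrated stress response genes rose, 11 of 20 (15; 0.97, 3.26e-09). These 6 lists had an adjusted p of 0.222 with an estimated correlation.

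Oxidative phosphorylation genes (0 of 25; -0.21, 0.00816) and histones (1 of 64; -0.24, 0.0159) fell and ribosomal proteins (1 up and 1 down of 78; 0.21, 0.0132) rose as lists in ΔTFR5, with 0, 0, and 1 and 1 over the list alone and an adjusted p of 0.8 with an estimated correlation. Without empty vector replicate 3 the first was at 0.0821 and histones at 0.137; histones were at 0.0945 without ΔTFR5 replicate 1 and 0.0754 without ΔTFR5 replicate 3. Ribosomal proteins were at 0.052 and 0.0919 without empty vector replicates 1 and 2 and 0.0888 without ΔTFR5 replicate 2. The count of 1907 was 5635 with the 2 groups alone (2704 higher and 2931 lower), 629, 667 and 527 without empty vector replicates 1, 2 and 3, 4600 without FL replicate 1, 3467 without FL replicate 3, and 571 and 440 without ΔTFR5 replicates 1 and 2 (304 and 136 in the latter).

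ΔTFR5 against ΔTFR4 tests directly how the deletions differ. SERPINA3 was higher in ΔTFR5 by 5.94 ± 0.30 (adjusted p = 5.32e-07), A2M by 4.24 ± 0.31 (1.67e-05) and GAS7 by 3.86 ± 0.32 (3.92e-05). TENM1 was lower, at -3.24 (1.8e-05), as was DLGAP1 at -2.56 ± 0.25 (0.000139). In all 85 genes were called, 67 higher and 18 lower (78.8% higher; DESeq2 139 and 77, 64.4%). The 2 groups alone gave 558 and 548 (50.5%), and leaving out FL replicate 3 gave 206 and 181 (53.2%). Lists with lower values in ΔTFR5 were p53 targets (median -0.41, adjusted p = 1.53e-11; 8 over the list alone), the integrated stress response (-0.31, 0.000812), markers of other cell types (-0.63, 0.00165; 3 over the list alone), MAPK output (-0.22, 0.00479), NF-kB targets (-0.37, 0.0105; 2 over the list alone) and SLNCR-linked genes (-0.63, 0.0105; 1 over the list alone). Lists with higher values were cell cycle (0.43, 6.66e-09), mitochondrially encoded (0.48, 2.89e-05) and extracellular matrix genes (0.17, 0.0377; 2 of 26 called, 3 up and 1 down over the list alone). No member of the other 8 lists was called over all genes, and where no count is given none passed over the list alone. With an estimated correlation the smallest adjusted p of these 9 lists was 0.191.

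Without ΔTFR5 replicate 3 the adjusted p in ΔTFR5 against ΔTFR4 was 0.204 for NF-kB targets and 0.295 for extracellular matrix genes; for the latter it was 0.146 and 0.0565 without ΔTFR4 replicates 2 and 3 and 0.0651 without ΔTFR5 replicate 1. The count of 85 was 203 without FL replicate 1, 387 without FL replicate 3, 39, 39 and 46 without ΔTFR4 replicates 1, 2 and 3, and 43 without ΔTFR5 replicate 3. Hypoxia, unfolded protein response and neuronal and axon guidance genes passed as lists in none of the 12 comparisons by camera; in ΔTFR4 and ΔTFR5 against empty vector melanocyte genes passed by fry and not by camera, upward (adjusted p = 0.0389 and 0.0374), and androgen response genes downward (0.0226 and 0.0325), as did neuronal genes downward (0.0364) and SLNCR-linked genes upward (0.0226) in ΔTFR4. No list call in any of the 12 comparisons held with an estimated correlation. Signs of median, mean and test differed for 7 lists in FL against empty vector, 4 in ΔTFR1 against FL and 2 in ΔTFR2 against FL in batch 1, and for 4, 0 and 4 lists in FL against empty vector, ΔTFR4 against FL and ΔTFR5 against FL in batch 2, none of them past the test.

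Reversed genes were also counted in batch 2. Of the 217 called in FL against empty vector, 14 (6.5%) were called the other way in ΔTFR4 against FL and 11 (5.1%) in ΔTFR5 against FL. These numbers were 1023 and 2253 without FL replicate 3, 3 to 9 and 2 to 5 without any 1 of the other libraries, 78 and 234 by DESeq2 and 36 and 61 with GC trends removed. MYOCD, a coactivator of muscle genes, lay at 3.58 ± 1.48 CPM with FL (63 to 162 counts), against 0.0451 with empty vector, 0.0258 with ΔTFR4 and 0.0509 with ΔTFR5 (0 to 2 counts per library). CTNND2 fell with FL and rose with ΔTFR4 by 1.18 (0.00227). ERBB3, a growth factor receptor of the melanocyte lineage, fell with FL by 0.66 ± 0.13 (0.0431) and rose with ΔTFR5 by 1.44 ± 0.13 (0.000855).

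Simulated batch 2 groups held no change or GC trend, so their 0 reversed genes tell little. For ΔTFR4 independent lists would share 4.76 and 0.455 (observed 12 up then down, 2 down then up). For ΔTFR5 it was 1.07 and 0.198 (observed 6 and 5). The covariance of log2 fold changes was -0.0998 for ΔTFR4 against -0.079 simulated and -0.159 for ΔTFR5 against -0.0786. Against empty vector ΔTFR4 and ΔTFR5 shared 1666 genes in the same direction, 904 higher and 762 lower, where independent lists would share 128 and 101, and 13 in opposite directions, with a covariance of 0.42 against 0.0801 simulated. FL shared 182 same-direction genes with ΔTFR4 (164 and 18; independent lists 24.1 and 2.75) and 136 with ΔTFR5 (123 and 13; 10.6 and 1.12), with covariances of 0.333 and 0.274 against 0.081 and 0.0814. Against FL, ΔTFR4 and ΔTFR5 shared 136 same-direction genes (83 and 53; independent lists 2.94 and 2.57), with a covariance of 0.246 against 0.0777.

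The response to FL was compared between batches over 13057 genes tested in both. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.26 and Spearman's rho = 0.36, which was 0.14 with GC trends removed and 0.075 without FL replicate 1 of batch 2. Of the genes called, 19 were called in both batches, 12 higher in both and 7 in opposite directions, where independent lists would share 19.3 higher in both and 2.61 lower in both. By DESeq2 283 were called in both, 185 higher and 49 lower in both (128 and 46.4 for independent lists), and by edgeR without FL replicate 3 of batch 2 these were 1281, 623 and 531 (319 and 279). Without any 1 of the other FL and empty vector libraries 0 to 20 were called in both by edgeR. CREB5 rose by 0.42 in batch 1 and 2.57 in batch 2 and the growth factor BMP2 by 0.52 and 1.93. Neither kept its batch 1 call with GC trends removed, at 0.25 (0.304) and 0.59 (0.0598). Genes that rose or fell with FL in batch 1 had medians of 0.23 and -0.26 in FL against empty vector of batch 2 (adjusted p = 2.22e-08 and 1.1e-13), of -0.31 and 0.14 in ΔTFR4 against FL (2.32e-20 and 9.6e-06) and of -0.29 and 0.12 in ΔTFR5 against FL (4.82e-19 and 7.57e-05). With an estimated correlation each had an adjusted p = 0.802.

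In ΔTFR4 against empty vector these medians were -0.07 and -0.12 (adjusted p = 0.0293 and 0.064) and in ΔTFR5 against empty vector -0.05 and -0.13 (0.0524 and 0.00267). These were 0.802 too with an estimated correlation. With GC trends removed the genes that rose in batch 1 had a median of 0.02 in FL against empty vector of batch 2 (adjusted p = 0.642) and those that fell had -0.12 (0.000615), while in ΔTFR4 and ΔTFR5 against FL the former had -0.14 and -0.11 (2.4e-05 and 0.00012) and the latter -0.04 and -0.03 (0.585 for both). Genes that rose with FL in batch 2, of which 159 were tested in batch 1, had a median of 0.03 in FL against empty vector there (adjusted p = 0.49). Genes that fell in batch 2, of which 22 were tested, had a median of 0.08 in ΔTFR2 against empty vector (adjusted p = 0.0132; adjusted p = 0.802 with an estimated correlation), and the other 9 tests of batch 2 genes in batch 1 had an adjusted p of 0.272 or higher.

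In batch 2 the first principal component, with 30% of the variance, was set against the SLNCR level over the 9 libraries with a construct; this relation was chosen after the data were seen. Spearman's rho was 0.83 (exact permutation p = 0.00827, adjusted 0.0165) and Pearson's r 0.68 (exact permutation p = 0.0427, adjusted 0.0854), among 2 relations, 1 per batch. Of 9 pairs of libraries within a group, 8 had the same order in both measures. Without ΔTFR5 replicate 3 and FL replicate 1, which lie farthest from the median SLNCR level, rho was 0.71 (exact permutation p = 0.0881) and r was 0.6 (0.145), coefficients of similar size that did not pass the test over 7 libraries. In batch 1 rho was 0.35 (exact permutation p = 0.359, also adjusted) and r was 0.22 (0.518), and without the 2 FL libraries farthest from the median they were 0.68 (0.11) and 0.8 (0.0234).

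**Figure D4:**
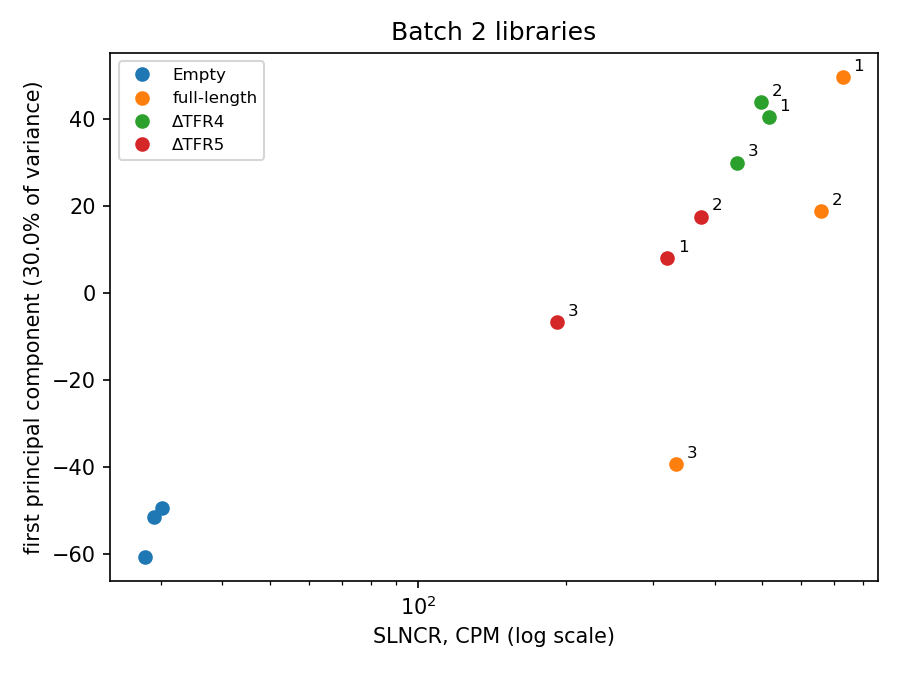
First principal component of batch 2 (30% of the variance) against SLNCR level in CPM (log axis); each point is a library, colours mark groups and numbers replicates. Over the 9 libraries with a construct Spearman's rho is 0.83.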

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

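The removal of GC trends and the GC test of the ΔTFR4 response were chosen after the results were seen; the other tests of this part were set before.

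The effect of FL against empty vector differed between the batches for 1084 genes by a test of the difference itself (z from both estimates and standard errors, adjusted p under 0.05). In 705 of them the effect was higher in batch 2 and in 379 it was lower. DYSF, a membrane repair gene, changed by -0.20 in batch 1 and 1.64 in batch 2 (adjusted p = 1.78e-08), STC2 by -0.28 and 1.95 (3.53e-06), TRIB3 by -0.24 and 1.68 (1.17e-05), the developmental factor SOX11 by 0.04 and 1.46, and RTN1 by 0.01 and -1.16. The number was 473, 425 and 388 without empty vector replicates 1, 2 and 3 of batch 2, 247 without FL replicate 2, 4143 without FL replicate 3, 518 by DESeq2 and 1987 with GC trends removed. Batch and quantification method changed together, so they cannot be told apart here.

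In batch 1, FL gave 3247 genes with small differences that follow GC content. Removing each library's GC trend left 8.7% of that number, below a limit of 20% for a trend as the cause. Over the 3247 genes the median absolute log2 fold change went from 0.26 to 0.09 and the median standard error from 0.0701 to 0.0604. Calls thus ended because the differences shrank. Without FL replicate 3, 53% were left (1721 genes), a little above the 50% set beforehand, which argues against that library alone; 1182 and 1934 were left without empty vector replicates 1 and 2. Genes that rose with FL in batch 2 had a median of 0.03 in batch 1 (camera over 159 genes, adjusted p = 0.49, 0.392 unadjusted), and since a p that misses the threshold does not show that the list stayed unchanged, a response shared by both batches stays open. A GC trend from library preparation may thus account for most of this number, and an effect of FL on GC-rich genes stays open, since all 3 FL libraries carry the trend.

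In batch 2, FL replicate 1 stood apart from the other libraries. With its GC trend removed the SD over genes of its deviation from the batch mean was 0.697, against 0.55 at most in the others, which argues against GC content as the whole cause. Olfactory receptor genes, silent in most cells, gave 298 CPM in it over 191 GC-richer genes (155 at most elsewhere). The 192 GC-poorer ones gave 61.1 (26.8 at most). Their median GC was 43.3% (tested genes 48.4%), so the GC trend may raise both. Genomic DNA stays open, and no biological cause was tested.

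In batch 2, ΔTFR4 against empty vector called 4489 genes. If the cells had differed in chromosome copy number, over 50% of called genes would lie in shifted windows of 50 neighbouring genes; 2.2% did (95 of 4338, in 6 of 357 windows). A GC trend would lower the number on removal, and it rose to 135% of 4489. The share in shifted windows and this rho argue against those causes. Still, the number was 2309 to 2914 without any 1 of the ΔTFR4 or empty vector libraries and 7329 without FL replicate 1. What stays open is a response to ΔTFR4 itself, to its SLNCR level or to transfection and selection, which could differ between groups.

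Each 3 against 3 comparison has 10 splits, too few for a share under 0.05. In a fit of these 6 libraries the real split gave 2108, 304 and 724 genes for FL against empty vector, ΔTFR1 against FL and ΔTFR2 against FL in batch 1, with 0 as the highest other each. It gave 2, 33, 1, 9081, 5635 and 1106 in batch 2 (FL against empty vector, ΔTFR4 and ΔTFR5 against FL, ΔTFR4 and ΔTFR5 against empty vector, ΔTFR5 against ΔTFR4), with 1, 1, 0, 0, 0 and 2 as the highest other. In each of these 9 comparisons 1 of the 10 splits, the real one, gave as many. For ΔTFR1 and ΔTFR2 against empty vector the real split gave 1 and 5, the highest other 8 and 46, and 3 of 10 splits gave as many; for ΔTFR2 against ΔTFR1 it was 0 (edgeR, 718 at an unadjusted p under 0.05), 35 and 10 of 10. Splits that call several times the real number point to a structure of these samples other than their groups.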

How the results depend on the processing

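The removal of GC trends and of GC and length trends was chosen after the results were seen. Of the counts, lists and correlations that answer a comparison, 122 of 198 values kept their side of the threshold or stayed within 1.5 times under settings chosen before the data were examined, 179 of 312 with 1 library left out and 45 of 80 with trends removed. For the other values, most of them single genes and lists, these were 1627 of 1957, 3626 of 4860 and 450 of 810; 224, 1117 and 292 lost their call with the same direction and 101, 93 and 44 gained one. The SLNCR level of each group stayed within 1 SD whichever library was left out. Where no reason is given, the cause was not tested. Simulated 2-fold changes in FL against empty vector were found for 84% of genes in batch 1 and 60% in batch 2, whose libraries were deeper and whose common biological coefficient of variation was 0.212 against 0.05. MMP9 was too low to test.

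By DESeq2, batch 2 gave 1947 genes in FL against empty vector, 1868 in ΔTFR4 against FL, 1399 in ΔTFR5 against FL, 2877 in ΔTFR5 against empty vector and 216 in ΔTFR5 against ΔTFR4. Reversed genes were 78 for ΔTFR4 and 234 for ΔTFR5, and 4 lists passed in ΔTFR2 against empty vector. With no filter, batch 2 gave 907, 486 and 141 genes in FL against empty vector, ΔTFR5 against FL and ΔTFR5 against ΔTFR4, with 35 (ΔTFR4) and 57 (ΔTFR5) reversed. In batch 1 it gave 2, 4 and 2 genes in ΔTFR1 against empty vector, ΔTFR2 against empty vector and ΔTFR2 against ΔTFR1, 4 lists in FL and 5 in ΔTFR2 against empty vector.

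With GC trends removed, batch 1 gave 281, 10 and 30 genes in FL against empty vector, ΔTFR1 and ΔTFR2 against FL, 9 and 23 reversed, and 4 lists in ΔTFR2 against empty vector. Batch 2 gave 774, 1453 and 868 genes in these main comparisons, 3335 in ΔTFR5 against empty vector, and 36 and 61 reversed. With GC and length trends removed these numbers were 301, 13 and 60, 11 and 44, and 4; 835, 1471 and 842, 3367, and 40 and 65. The lists past the test were then 1 in ΔTFR1 against FL and 0 in ΔTFR2 against ΔTFR1. The correlation of FL effects between batches was 0.135 and 0.129, and 0.484 over genes with a mean log2 CPM of at least 3. Genes that differ between batches were 1987 and 2026, and 518 by DESeq2. Genes called in both were 6 with either removal and 283 by DESeq2. These settings remove the trend that the batch 1 numbers follow. Among genes called in the other batch, rising genes lost their call in FL against empty vector of batch 2 (0.642), and falling genes had an adjusted p of 0.585 in ΔTFR4 and in ΔTFR5 against FL with the direction turned, 0.00607 in ΔTFR4 against empty vector, and rising genes 0.00789 in ΔTFR5 against empty vector.

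Called genes that changed sign lay near 0 after removal. In FL against empty vector of batch 1, with GC removed, CYC1 was at 0.006, ETV4 at 0.006, FOSL1 at 0.04, INHBA at -0.002, KIF11 at -0.008, SLC7A5 at 0.067 and TNFAIP2 at 0.013, and FOSL1 at -0.01 in ΔTFR2 against FL. With length removed too, CYC1 was at 0.032, ETV4 at 0.004, FOSL1 at 0.045, INHBA at -0.007, KIF11 at -0.018, RPS15 at 0.032, SLC7A5 at 0.056 and TNFAIP2 at 0.003, HIST1H3D at -0.074 in ΔTFR1 against FL and FOSL1 at -0.021 in ΔTFR2 against FL.

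The 2 compared groups alone gave 2108, 304, 724 and 5 genes in batch 1 (main comparisons, then ΔTFR2 against empty vector). In batch 2 they gave 2, 33 and 1 in the main comparisons (with FL) and 9081, 5635 and 1106 in the others. Chi-square per gene was 67.6 to 221 between FL replicates and at most 42.05 in other groups, so the shared spread may understate FL's. A log2 fold change of at least 1 left 22, 12, 10 and 1 genes in batch 1. It left 324, 132, 1792 and 697 in ΔTFR4 and ΔTFR5 against FL and against empty vector.

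Pairing by replicate number stays open: in each batch 6 of 12 libraries correlated best with their own number. Correlations were -0.13 to 0.18 in batch 1 and -0.14 to 0.2 in batch 2. With the number as a block, ΔTFR1 and ΔTFR2 against FL gave 2231 and 2178 genes in place of 1440 and 1432, with 1932 and 1902 reversed. In batch 2 the block gave 399 in FL against empty vector and 170 in ΔTFR5 against FL, where 23 of 31 called genes the naming rule took passed, and 48 genes called in both batches in place of 19; it moved no other count of called genes, reversed genes or lists in a comparison by over 1.5 times.

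By camera with an estimated correlation between genes, 0 lists passed in any comparison (smallest adjusted p per comparison 0.0566 to 0.793), and the other-batch lists that had passed were at 0.802 as adjusted p. With camera at the preset correlation 1 to 12 lists had passed. By fry 6, 0 and 1 lists passed in FL against empty vector, ΔTFR1 and ΔTFR2 against FL, and 0, 1 and 0 in the secondary comparisons of batch 1. In batch 2 it was 6, 2 and 3 in the main comparisons and 2 in ΔTFR5 against ΔTFR4.

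Leaving out 1 library gave, as lowest and highest, 1182 and 4064 genes in FL against empty vector, 22 and 2752 in ΔTFR1 and 0 and 2710 in ΔTFR2 against FL (0 without ΔTFR2 replicate 2, edgeR, 2802 at an unadjusted p under 0.05), 1 and 1, 1 and 3, and 0 and 0 in the secondary comparisons of batch 1. In batch 2 they were 6 and 5966, 79 and 2220, 19 and 3480, then 2309 and 7329, 440 and 4600, and 39 and 387. Reversed genes were 22 to 2472 (ΔTFR1), 0 to 2455 (ΔTFR2), 3 to 1023 (ΔTFR4) and 2 to 2253 (ΔTFR5). Lists past the test were 2 to 3, 1 to 3, 2 to 3, 1 to 6, 2 to 4 and 0 to 2 in batch 1 and 10 to 13, 4 to 10, 6 to 10, 8 to 11, 7 to 9 and 7 to 10 in batch 2. The correlation between batches was 0.075 to 0.47, genes that differ between batches 247 to 4143 and genes called in both 0 to 1281 (edgeR). SLNCR levels were 19.75 to 20.71, 192.5 to 230.0, 194.1 to 201.2 and 189.5 to 199.1 CPM in batch 1 and 28.47 to 29.59, 496.2 to 693.2, 470.9 to 506.5 and 256.2 to 348.3 in batch 2.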

Other observations

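The test of the SLNCR level was chosen after the result was seen. In batch 2, libraries of one group did not respond alike. FL replicate 3, with 334.1 CPM of SLNCR, lay at -39.4 on the first principal component, near the empty vector libraries at -60.7 to -49.4, while FL replicates 1 and 2, at 728.1 and 658.3 CPM, lay at 49.6 and 18.8. ΔTFR5 replicate 3, with 191.6 CPM, lay at -6.8, below ΔTFR5 replicates 1 and 2 at 7.9 and 17.5. Without FL replicate 3, FL against empty vector gave 5966 genes in place of 217.

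A hypothesis is that the response of batch 2 follows in part the SLNCR level a library reached. Over the 9 libraries with a construct the first component went with the level (Spearman, exact permutation p = 0.00827), in a test that treats libraries of different groups as exchangeable. Spearman's rho was 0.83, and 0.71 without ΔTFR5 replicate 3 and FL replicate 1, the libraries farthest from the median level (exact permutation p = 0.0881), so the test did not pass over 7 libraries while rho stayed similar in size. The level may also stand for the amount of plasmid taken up or for survival in puromycin, neither of which was measured. Other values go against the level alone: the ΔTFR4 libraries, at 443.9 to 515.1 CPM, lay at 29.9 to 43.8, above FL replicate 2, and FL replicate 3 lay below ΔTFR5 replicates 1 and 3, which had less SLNCR (320.8 and 191.6 CPM). The region deleted thus stays open. SERPINA3 did not follow the level between these groups: FL and ΔTFR4 had 574 ± 210 and 486 ± 37.2 CPM of SLNCR and 11.7 ± 2.48 and 0.556 ± 0.031 CPM of SERPINA3 (SD, n = 3).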
